A study of Mus musculus with 9 samples.

How the data were processed

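Gene expression was measured in granulocyte-monocyte progenitors (GMPs), the marrow cells that give rise to neutrophils and monocytes. Per the labels, they were sorted from mouse bone marrow as lineage-negative, Kit-positive, Sca1-negative, CD16/32-positive and CD150-negative cells, and total RNA was labelled with the single dye Cy3 and measured on Agilent gene expression arrays for mouse (SurePrint G3, 8x60K). The marrow came from C57BL/6 recipients 1 month after they were given either wild-type (WT) bone marrow or spleen cells of 1 of 2 moribund mice with leukaemia. Those mice lacked Tet2 and carried AE, the AML1-ETO fusion of Runx1 with Runx1t1. The leukaemias are called LeuA and LeuB. Each of the 3 groups has 3 arrays, called biological triplicates in the labels. Whether an array holds RNA of 1 recipient or of a pool is not stated in the labels. For the LeuB arrays the field on the transplanted cells names LeuA, whereas title and source name LeuB, and the grouping followed title and source.

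The arrays lay on 2 slides. The first held the 3 WT arrays in its upper row and the 3 LeuA arrays and LeuB 1 in its lower row, and the second held LeuB 2 and LeuB 3 in its upper row. Replicate numbers were tested as pairs across groups. After removal of group means, the 9 pairs of same-numbered arrays correlated across genes between -0.041 and 0.103, and 1 of them exceeded 0.1. For 4 of the 9 arrays the best partner in another group had the same number, so the numbers were not used as pairs.

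The deposited values are log2 intensities between 5.66 and 18.24 for 37877 probes. Per the submitters' processing notes, RMA, affy and limma were used, with no versions and no roles given, and neither background correction nor detection flags are described. The values had already been brought to a common distribution: array medians lay between 7.02 and 7.04, and a further quantile normalization moved values by at most 0.06. They were used as deposited. The depth of an array is not a count, so the number of arrays limits the precision here.

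Probes were assigned by the probe-to-gene table supplied with the series. 24877 probes had 1 gene symbol, 0 had several, and 13000 had no gene name in the table used here. Of the probes with a name, 24606 were matched by gene identifier to a table of mouse gene names, which changed 0 symbols. Probe positions were not used here. This gave 21872 genes, of which 2637 had more than 1 probe. Each was represented by the probe with the highest mean over all arrays. No filter on dim probes was applied.

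Groups were compared with limma 3.58.1 in R 4.3.3, and values were read with the data.table package, version 1.17.8. A linear model of group means was fitted to all 9 arrays with lmFit, and eBayes was run with its defaults. The prior had 3 degrees of freedom beside 6 residual ones, and the median residual SD was 0.112. Tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 21872 genes. The 3 comparisons were LeuA against WT, LeuB against WT, and LeuB against LeuA. Genes called in the same direction in both leukaemias were counted beside the overlap of independent lists and beside 20 simulations of unchanged groups that share 3 control arrays.

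Before the data were examined, 28 gene lists were fixed from general knowledge of the tissue and genotype: primary granule and GMP genes, secondary granule and mature neutrophil genes, monocyte and macrophage genes, MHC class II and dendritic cell genes, haematopoietic stem cell genes, HoxA and Meis genes, myeloid transcription factors, erythroid genes, megakaryocyte genes, mast cell, basophil and eosinophil genes, B cell genes, T cell and NK cell genes, cell cycle genes, CDK inhibitors, interferon-stimulated genes, NF-kappaB target genes, immediate early and stress genes, DNA methylation machinery, genes linked to activation by AML1-ETO, genes linked to repression by AML1-ETO, BCL2 family, MYC and ribosome biogenesis genes, glycolysis and hypoxia genes, adhesion and homing genes, cytokine receptors and signalling, sort gate genes, sex-linked transcripts and housekeeping genes. Of the 403 genes on them, 377 were measured. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over 84 tests, which are the 28 lists in the 3 comparisons. The same tests were run with a correlation estimated per list, and with fry.

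The genes named in the text follow a rule fixed before the data were examined. Tet2, Tet1, Tet3, Runx1, Runx1t1, Kit, Fcgr3, Fcgr2b and Slamf1 are always named. For each leukaemia against WT the 6 genes with the largest rise and the 6 with the largest fall were taken, and for LeuB against LeuA 8 and 8. These had to be called, to have all arrays of one group on one side of those of the other, and to have the higher group mean above 7.53, the median of all gene means. Unnamed gene models and antigen receptor segments were skipped. For each list, up to 4 called members with the largest mean change in the leukaemias were taken. This gave 137 genes. Genes outside the rule are named only where the text says that they were chosen after their values were seen.

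The model was tested on simulated data with planted changes. For LeuA against WT it found 49.3% of genes changed by 0.5 on the log2 scale, 82.1% of those changed by 1 and 98.5% of those changed by 2, and 3.8% of its calls were false. For LeuB against WT it found 56.7%, 85.1% and 97%, with 5.4% of calls false, and for LeuB against LeuA 49.3%, 88.1% and 95.5%, with 3.7% false. In each comparison camera called the 1 planted list, and the unchanged lists it called numbered 0. The simulated genes varied independently of each other, and each simulation was run a single time. In the real lists the estimated correlation reached 0.59. So these rates do not show how the tests behave when genes vary together.

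The choices tried as alternatives were the normalization (quantile again, or centring on the median), a filter on dim genes (at a lower or a higher level, the latter the median), the probe rule (mean of probes, or every probe), the variance model (intensity trend with robust settings, or array weights), the arrays in the model (only the groups compared, or slide 1 only), slide or replicate number as a block, the threshold, and the omission of each array in turn. These were fixed before the data were examined. Without LeuB 1 all LeuB arrays lie on the second slide and all other arrays on the first. In that fit slide and group cannot be told apart for LeuB. The omission of WT 1 together with LeuB 3 was added after seeing the data. All splits of the arrays compared into groups of 3 and 3, or 100 splits of the 9 arrays, were also run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

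Probes with no gene name were left out of the gene-level tests and are counted only among the other observations and the results for a closer look. List genes with no value here include Ly6a, which encodes Sca1, so that marker of the gate was not analysed here.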

Results

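The data are expression profiles of GMPs sorted from recipients of WT bone marrow and of cells of the leukaemias LeuA and LeuB, with 3 arrays per group and 9 in all. LeuA and LeuB arose independently in mice without Tet2, whose product oxidizes methylated cytosine in DNA, and with the AE fusion. The comparisons with WT ask how the leukaemic GMPs differed from normal ones, and the comparison of LeuB with LeuA asks where the leukaemias differed from each other. Values are log2 intensities for 21872 genes, and each group mean rests on n = 3 arrays. All arrays shared a distribution with medians of 7.02 to 7.04 and a highest value of 18.24. The replicates of a leukaemia descend from 1 primary mouse, so the p-values measure the spread among these arrays, not among leukaemias. The leukaemic grafts came from spleen and the WT graft from marrow, so donor tissue changed together with genotype.

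WT and leukaemic GMPs formed separate clusters. The first principal component, computed across genes, held 82.3% of the variance and placed the WT arrays between -101.6 and -98.8 and the 6 leukaemic arrays between 48.9 and 51.9. The second held 8.2% and separated LeuA (23.4 to 31.6) from LeuB (-32.4 to -17.3). Correlations across genes, which are not independent replicates, were 0.991 to 0.997 within groups, 0.982 to 0.989 between the leukaemias, and 0.908 to 0.914 between WT and leukaemic arrays. LeuB 1 lay on the slide of the WT and LeuA arrays and the other LeuB arrays on a second slide. The median absolute difference per gene between LeuB 1 and LeuB 2 was 0.22, and between LeuB 2 and LeuB 3 it was 0.113.

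Transcripts of Tet2 were still read by the arrays in both leukaemias. The brightest Tet2 probe gave 9.26 ± 0.06 (SD, n = 3) in WT, 9.38 ± 0.07 in LeuA and 9 ± 0.04 in LeuB. The difference from WT was 0.12 (SE 0.06, adjusted p = 0.2) in LeuA, and in LeuB Tet2 fell by 0.25 (SE 0.06, adjusted p = 0.011). The second Tet2 probe gave -0.03 and 0.05, with adjusted p of 0.92 and 0.82. Where the probes lie relative to the deleted part of the gene was not examined. The fall in LeuB was lost with slide as a block (-0.20, adjusted p = 0.117) and with the mean of both probes (-0.10, adjusted p = 0.313). Tet1, a second gene of the family, fell by 2.93 in LeuA and by 3.01 in LeuB (SE 0.10), from 9.30 to 6.38 and 6.29, whereas its other probe gave -0.36 and -1.08 with adjusted p of 0.69 and 0.13. Tet3 gave 0.16 (adjusted p = 0.38) in LeuA and rose by 0.51 (SE 0.12, adjusted p = 0.007) in LeuB. The Tet3 call in LeuB was lost with slide as a block (0.185, adjusted p = 0.078), where LeuB 1, at 7.17 against 7.65 in both other LeuB arrays, is the LeuB array on the slide of WT, and without LeuB 1 Tet3 was called in LeuA (adjusted p = 0.0318).

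Both partner genes of the fusion were higher in the leukaemias. Runx1, which encodes AML1, rose by 2.05 in LeuA and by 1.14 in LeuB (SE 0.07), from a WT mean of 10.67. Runx1t1, which encodes ETO, rose by 2.07 in LeuA (SE 0.25, adjusted p = 0.00012) and by 0.87 in LeuB (adjusted p = 0.02). Whether these probes read the fusion transcript was not examined. The Runx1t1 call in LeuB was lost with slide as a block (0.53, adjusted p = 0.306), without WT 1 (adjusted p = 0.0618), without LeuB 2 (0.0673) and without LeuB 3 (0.0754).

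Among genes of the sort gate, Kit, the stem cell factor receptor, gave -0.17 in LeuA and -0.22 in LeuB (SE 0.09), with adjusted p of 0.21 and 0.088. Transcripts of both CD16/32 receptors, which the gate requires, fell. Fcgr3 fell by 1.78 in LeuA and by 1.43 in LeuB (SE 0.20), and Fcgr2b by 1.64 and by 0.96 (SE 0.07). Slamf1, which encodes the excluded CD150, gave 0.19 in LeuA (adjusted p = 0.27) and rose by 0.83 in LeuB (SE 0.12, adjusted p = 0.00029), from 6.06, near the bottom of the scale. The sort gate list joins markers that the gate requires with Slamf1, which it excludes, and with lineage genes and Ptprc. Its joint result is therefore not a measure of the required markers. Of 7 measured genes on the list, 5 fell in LeuA, and 5 fell and 1 rose in LeuB. When adjusted over the list alone, 6 fell in LeuB. Its medians were -0.29 and -0.50, with camera adjusted p of 0.019 and 0.044, and adjusted p = 0.23 and 0.26 with an estimated correlation. Without LeuB 1 the call in LeuB was lost (adjusted p = 0.0884), and the LeuA count was 3 without WT 1, WT 3, LeuA 2, LeuA 3 or LeuB 2. The sorted cells were of 1 sex by their transcripts. Xist, which is read from the inactive X chromosome, had means of 10.66, 10.34 and 11.07 in WT, LeuA and LeuB. The Y-linked Eif2s3y, Kdm5d and Uty lay between 5.97 and 6.14. The 4 measured sex-linked transcripts had medians of 0.03 in LeuA and 0.12 in LeuB, with camera adjusted p of 0.88 and 0.69, and in LeuA their mean of -0.04 had the opposite sign. Without LeuB 1, where slide and group coincide for LeuB, Kdm5d was called in LeuB (adjusted p = 0.0265) at this low level.

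**Figure D1:**
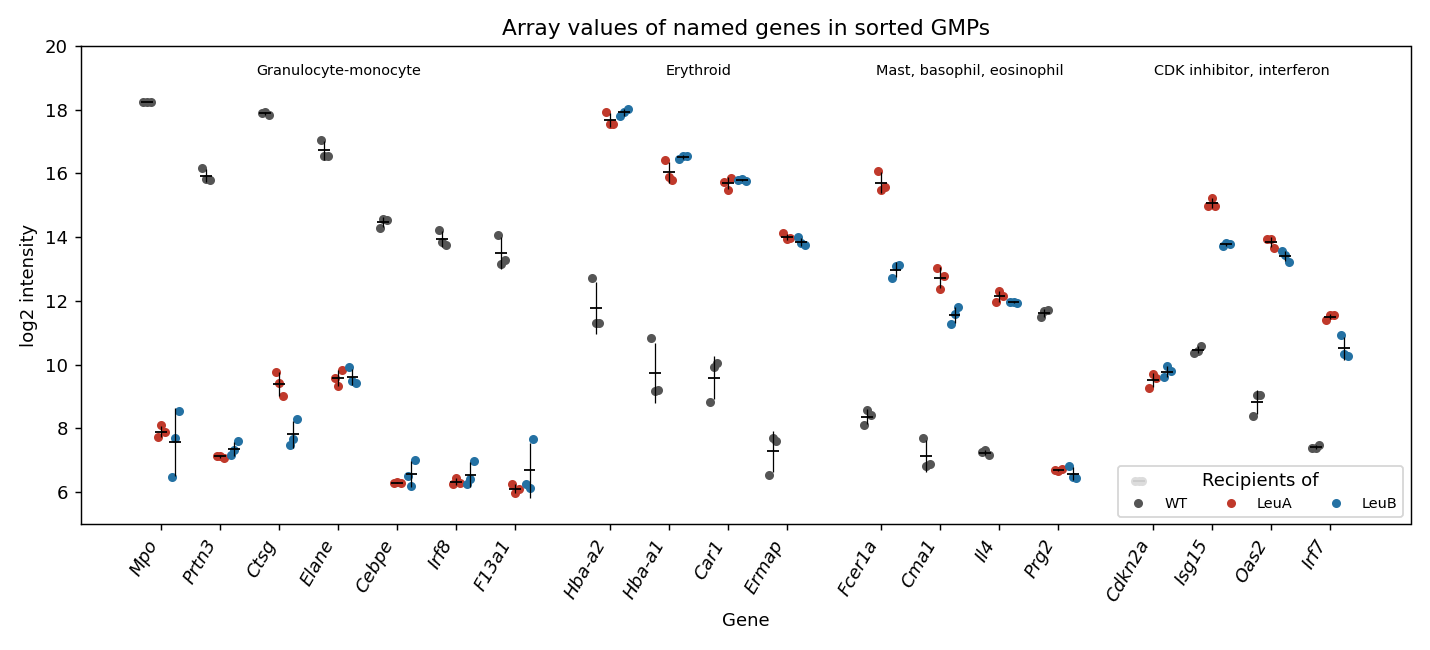
Log2 intensity of named genes in each array of WT, LeuA and LeuB, with points for arrays and the mean and SD of each group. Mpo lies at 18.24 in all WT arrays and at means of 7.90 in LeuA and 7.57 in LeuB.

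Genes of neutrophil granules were among the largest falls in LeuA. Mpo, the myeloperoxidase of neutrophil granules, was at 18.24, the top of the scale, in all 3 WT arrays. It was at 7.90 ± 0.17 (SD, n = 3) in LeuA, 1300-fold lower in these values. The highest value was 18.24 in every array, so it marks the top rank of a shared distribution. The Mpo fold may therefore be understated or overstated. The second Mpo probe gave -10.97 on the log2 scale. The granule proteases Prtn3 (448-fold) and Ctsg (360-fold), the surface antigen Ly6c1 (353-fold), Plppr3 (337-fold) and Cebpe (288-fold), a transcription factor of granulocyte maturation, were also lower. The largest rises under the naming rule were in the prion protein gene Prnp (382-fold), in Tph1 (319-fold) and Ddc (317-fold), which encode the enzymes that make serotonin from tryptophan, in Bex4 (224-fold) and Sapcd1 (191-fold), and in the beta-globin gene Hbb-b2 (176-fold). Several rises started near the bottom of the scale, with WT means of 6.51 for Tph1, 6.78 for Ddc and 6.98 for Prnp. No background level was used here, so these folds are ratios of intensity. As the naming rule required, each of these 12 genes was called and had all LeuA arrays on one side of all WT arrays. The adjusted p lay between 4.6e-12 and 3.9e-07. The second Plppr3 probe gave -0.09 and was not called.

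In LeuA against WT 8049 of 21872 genes (36.8%) were called with limma, 3907 higher and 4142 lower. Of these, 2838 changed at least 2-fold (1356 higher, 1482 lower) and 178 at least 32-fold. The groups did not overlap in 10822 genes, where chance gives 10% of genes. With slide as a block the count was 8591.

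Granule genes were among the largest falls in LeuB and beta-globin genes among the largest rises. Mpo was 1630-fold lower in these values, at 7.57 ± 1.06 (SD, n = 3), with the same limit from its top rank in WT. Its second probe gave -10.95 on the log2 scale. Ctsg was 1080-fold, Prtn3 379-fold, Plppr3 306-fold, Ly6c1 299-fold and Cebpe 239-fold lower. On the log2 scale Ly6c1 changed by -8.22 (SD of 1.05 among the LeuB arrays), by -8.83 without LeuB 3 and by -8.95 with slide as a block, and Mpo by -10.67, or -11.79 with the block. Prnp was 421-fold, Hbb-bs 334-fold, Tac2 333-fold, Hbb-b2 316-fold, Ddc 261-fold and Sapcd1 210-fold higher. Hbb-bs is a beta-globin gene and Tac2 encodes a tachykinin, a small signalling peptide, and their WT means of 6.91 and 6.62 lie near the bottom of the scale too. Whether the probes of Hbb-bs and Hbb-b2 read separate transcripts was not tested. The adjusted p of these 12 genes lay between 6.3e-12 and 4.8e-07, and all LeuB arrays lay on one side of all WT arrays, as the naming rule required. The second Plppr3 probe gave -0.05 and was not called.

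In LeuB against WT 9241 genes (42.3%) were called, 4770 higher and 4471 lower. Of these, 3013 changed at least 2-fold (1516 higher, 1497 lower) and 161 at least 32-fold. The groups did not overlap in 11453 genes, where chance gives 10%. With slide as a block the count was 7106, of which 6646 were among the 9241, and on slide 1 alone, where LeuB has 1 array that is assumed to vary like the other groups, it was 6776.

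The gene groups below are given for LeuA and LeuB against WT, with log2 changes in that order in brackets and the SE they share. Counts adjusted over the list alone equalled those over all genes tested except where a second count is given. Of the 84 list tests, camera called 24, of which 12 were in LeuA, 10 in LeuB and 2 in LeuB against LeuA. With an estimated correlation camera called 0, with 14 tests at an unadjusted p under 0.05 and a smallest adjusted p of 0.18, and fry called 60. So each list call named here was lost with an estimated correlation. That setting also tests on the 6 residual degrees of freedom and not on the number of genes, so it has less power here. Single members named because they went against their list (Lgals3, Ccr9, Aqp1, Cd22, Ly6e, Nr4a1 and Gbp2), and Id2, were chosen after their values were seen.

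Primary granule and GMP genes, a list of granule proteases and other GMP genes, fell in both leukaemias, 11 of 12 measured in LeuA and 12 of 12 in LeuB. The medians were -6.76 and -6.72, with camera adjusted p of 2.1e-10 and 6e-10, and adjusted p = 0.18 with an estimated correlation in each. Elane, neutrophil elastase, fell by 7.14 and by 7.11 (SE 0.19). Of 17 measured secondary granule and mature neutrophil genes, 12 fell in LeuA (14 adjusted over the list alone) and 7 in LeuB. The medians were -2.21 and -1.76, with camera adjusted p of 3e-04 and 0.0029, and adjusted p = 0.46 and 0.54 with an estimated correlation. Examples are the calprotectin gene S100a8 (-4.72 and -4.60, SE 0.91), Padi4, an enzyme that citrullinates histones (-3.41 and -3.31, SE 0.08), and lipocalin Lcn2 (-2.63 and -2.44, SE 0.32). The S100a8 change in LeuB depended on the arrays, with -5.91 without LeuB 3, -3.64 without LeuB 1 and -6.50 with slide as a block, and Lcn2 gave -3.06 without WT 1 and LeuB 3.

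The secondary granule and mature neutrophil genes also differed among arrays of a group. Ltf, lactoferrin, chosen after its values were seen, was at 7.35 in WT 1 against 10.49 and 10.43 in the other WT arrays. S100a9, the partner of S100a8, was at 12.99 in LeuB 3 against 7.89 and 9.18 in LeuB 1 and LeuB 2. The number of these genes that fell in LeuB was 12 without WT 1, 14 without LeuB 3 and 15 without both. In LeuA it was 5 without WT 2 or WT 3, 7 without LeuA 1, LeuA 2 or LeuA 3, and 14 without WT 1 and LeuB 3. S100a9 fell by 3.62 in LeuA and by 3.84 in LeuB (SE 1.17, adjusted p = 0.037 and 0.025), with -5.32 in LeuB without LeuB 3, -2.77 without LeuB 1 and -5.96 with slide as a block, and -4.46 in LeuA and -4.68 in LeuB without WT 1. Its LeuA call was lost without WT 2, WT 3, LeuA 1, LeuA 2, LeuA 3 or LeuB 2 (adjusted p 0.0521 to 0.117). The LeuB call of S100a9 was lost without WT 2, WT 3, LeuB 1 or LeuB 2 (0.0723 to 0.0905). With genes below the median left out, both camera calls of the list were lost (adjusted p = 0.0769 and 0.18).

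Of 14 measured monocyte and macrophage genes, 12 fell and 1, Lgals3, rose in each leukaemia. The medians were -3.42 and -3.08, with camera adjusted p of 1.2e-06 and 9.7e-06, and adjusted p = 0.41 and 0.42 with an estimated correlation. Irf8, a transcription factor that GMPs need to form monocytes, was 196-fold lower in LeuA and 169-fold lower in LeuB. The coagulation factor gene F13a1 (-7.41 and -6.83, SE 0.39), Ly86 (-5.51 and -5.60, SE 0.21) and Ms4a6c (-5.06 and -4.80, SE 0.13) fell too. Of 13 MHC class II and dendritic cell genes, 6 fell and 1, Ccr9, rose in each leukaemia, and 2 rose in LeuB without WT 2 or LeuB 1. The medians were -0.28 and -0.26, with camera adjusted p of 0.036 and 0.08, and adjusted p = 0.32 and 0.42 with an estimated correlation. LeuB was called as well with slide as a block (0.0406) and without LeuB 3 (0.0274), and with genes below the median left out the LeuA call was lost (0.0769). Among its members H2-Ab1 (-5.36 and -5.01, SE 0.26), H2-DMa (-4.05 in each, SE 0.07), H2-DMb1 (-3.41 and -3, SE 0.13) and the cytokine receptor gene Flt3 (-3.16 and -3.11, SE 0.10) fell. The second Flt3 probe gave -0.10 and -0.09 and was not called.

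Myeloid transcription factors fell on balance. Of 19 measured, 11 fell and 5 rose in LeuA, and 12 fell (14 adjusted over the list alone) and 4 rose in LeuB. The medians were -1.38 and -1.03, with camera adjusted p of 0.0044 and 0.0015, and adjusted p = 0.26 in each with an estimated correlation. With genes below the median left out, the LeuA call was lost (adjusted p = 0.0603). Cebpe (-8.17 and -7.90, SE 0.18), Cebpd (-6.79 and -6.74, SE 0.20) and Gfi1 (-6.63 and -6.54, SE 0.15), regulators of granulocyte formation, fell, as did Irf8. Members that rose in both leukaemias were Runx1, Runx1t1, Id1 and Id2.

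Erythroid genes were higher in both leukaemias. Of 18 measured, 14 rose and 1, Aqp1, fell in LeuA, and 16 rose and 1 fell in LeuB. The medians were 4.74 and 4.48, with camera adjusted p of 2.6e-08 and 4.4e-09, and adjusted p = 0.18 in each with an estimated correlation. Ermap, an erythrocyte membrane protein gene, was 106-fold higher in LeuA and 95.5-fold higher in LeuB. The alpha-globin genes Hba-a1 (6.30 and 6.78, SE 0.39) and Hba-a2 (5.89 and 6.15, SE 0.33) and the carbonic anhydrase gene Car1 (6.10 and 6.20, SE 0.27) rose. The Hba-a2 means were 11.77 ± 0.81 in WT, 17.67 ± 0.22 in LeuA and 17.92 ± 0.11 in LeuB (SD, n = 3). WT 1 stood apart in this list, with 3 genes higher and 4 lower by more than 1 than the mean of the other WT arrays. Hba-a1 was at 10.82 in WT 1 against 9.18 and 9.21, and Ermap at 6.54 against 7.71 and 7.59. Monocyte and macrophage genes had a median 0.69 higher in WT 1 than in the other WT arrays.

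Megakaryocyte genes went both ways. Of 13 measured, 3 rose and 6 fell in LeuA, and 3 rose (4 adjusted over the list alone) and 7 fell in LeuB. The medians were -0.03 and -0.70, with camera adjusted p of 0.48 and 0.37. The platelet glycoprotein gene Gp5 (4.76 and 5.09, SE 0.08) and Rab27b (4.31 and 4.35, SE 0.11) rose, and the integrin Itgb3 (-3.20 and -3.87, SE 0.12) and platelet factor Pf4 (-3.79 and -3.28, SE 0.22) fell. Of 16 mast cell, basophil and eosinophil genes, 7 rose and 5 fell in LeuA, and 7 rose (8 adjusted over the list alone) and 6 fell in LeuB. The medians were 0.89 and 0.71, with camera adjusted p of 0.19 and 0.4. Fcer1a, a chain of the high-affinity IgE receptor, was 162-fold higher in LeuA and 24.5-fold higher in LeuB. The mast cell chymase gene Cma1 (5.59 and 4.42, SE 0.26) and the cytokine gene Il4 (4.90 and 4.73, SE 0.09) rose as well, whereas the eosinophil granule gene Prg2 (-4.94 and -5.05, SE 0.11) fell.

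Of 17 haematopoietic stem cell genes, 5 rose and 7 fell in LeuA, and 6 rose and 7 fell in LeuB. Medians were -0.13 and -0.02, with camera adjusted p of 0.58 and 0.82, and in LeuA the mean of 0.02 had the opposite sign. Ctnnal1 (3.38 and 2.72, SE 0.09) and the transcription factors Tal1 (2.59 and 2.42, SE 0.12) and Gata2 (1.87 and 2.10, SE 0.24) rose, and the progenitor antigen Cd34 (-2.89 and -2.47, SE 0.13) fell. Of 13 HoxA and Meis genes, 6 fell and 1 rose in LeuA, and 7 fell and 1 rose in LeuB. The medians were -0.13 and -0.31, with camera adjusted p of 0.044 and 0.038, and adjusted p = 0.42 in each with an estimated correlation. The LeuA call of this list was lost without LeuA 2 (0.0522) or LeuA 3 (0.0587), the LeuB call with slide as a block (0.0713), and both with genes below the median left out (0.178 and 0.248). Hoxa7 (-5.50 and -5.26, SE 0.09) and Meis1 (-4.78 and -4.83, SE 0.12), which mark immature myeloid cells, fell, and Pbx3 (0.91 and 2.49, SE 0.09) rose. Hoxb4 fell (-2.59 and -2.87, SE 0.81), with 9.63 in LeuA 1 against 6.05 and 6.01 in the other LeuA arrays. Without LeuA 1, LeuA 2 or LeuA 3 the change in LeuA was -3.79, -2 or -1.98. Its LeuA call was lost without WT 1, WT 2, WT 3, LeuA 2, LeuA 3 or LeuB 2 (adjusted p 0.0528 to 0.112), and its LeuB call without WT 3 (0.0516), without LeuB 2 (0.054) and with slide as a block (0.0929).

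Of 13 B cell genes, 4 fell (5 adjusted over the list alone) and 1 rose in LeuA, and 4 fell and 1 rose in LeuB. The gene that rose, Cd22, was not called in LeuA without WT 1, WT 3, LeuA 1, LeuA 2, LeuA 3 or LeuB 2, nor in LeuB without WT 1, WT 3, LeuB 2 or LeuB 3 or with slide as a block. The medians were -0.20 and -0.11, with camera adjusted p of 0.11 and 0.32. The B cell receptor subunit Cd79b (-4.70 and -2.73, SE 0.20), Vpreb1 (-1.20 and -0.68, SE 0.15) and Igll1 (-0.49 and -0.66, SE 0.09) fell in both. Dntt, the terminal transferase, fell by 0.81 in LeuB (SE 0.16) and gave -0.39 in LeuA with adjusted p = 0.09, and it was called there without LeuB 1 (0.00244) or LeuB 3 (0.0498). Of 14 T cell and NK cell genes, 2 rose and 2 fell in LeuA, and 3 rose and 5 fell (6 adjusted over the list alone) in LeuB. The LeuB count of falls was 2 without WT 1, WT 2, WT 3 or LeuB 2, 3 without LeuB 3, and 2 with slide as a block. The medians were -0.04 and -0.12 and the means 0.04 and 0.15, with camera downward at adjusted p of 0.82 and 0.81. The transcription factor Gata3 (3.91 and 4.73, SE 0.10) and the adaptor Lat (3.10 and 4.10, SE 0.19), which mast cells also use, rose, and the granule genes Nkg7 (-4.27 and -4.59, SE 0.17) and Gzmb (-1.54 and -0.91, SE 0.30) fell. The Gzmb call in LeuB was lost without WT 1, WT 2, WT 3, LeuB 1 or LeuB 2 (adjusted p 0.0653 to 0.106).

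All 7 CDK inhibitors, which restrain the cell cycle, rose in both leukaemias. The medians were 1.41 and 1.44, with camera adjusted p of 0.00041 and 0.00015, and adjusted p = 0.18 in each with an estimated correlation. Cdkn2a, the p16 and p19 locus, was 8.98-fold higher in LeuA and 10.8-fold higher in LeuB. Cdkn2c (1.53 and 1.58, SE 0.09), Cdkn1b (1.41 and 1.44, SE 0.10) and Cdkn1c (1.11 and 1.46, SE 0.29) rose as well. The second Cdkn1b probe was not called in LeuA (0.34, adjusted p = 0.15). Of 24 cell cycle genes, 12 rose and 4 fell in LeuA, and 10 rose (12 adjusted over the list alone) and 7 fell in LeuB. The medians were 0.21 and 0.24, with camera adjusted p of 0.13 and 0.4. The proliferation marker Mki67 (1.15 and 1.20, SE 0.07) and the mitotic genes Plk1 (0.75 and 0.81, SE 0.15) and Ccna2 (0.70 and 0.84, SE 0.06) rose, and E2f1 (-0.68 and -1.05, SE 0.11), a transcription factor of S phase entry, fell.

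Interferon-stimulated genes were higher in both leukaemias. Of 21 measured, 19 rose (20 adjusted over the list alone) in LeuA and 17 (18) in LeuB, and 1, Ly6e, fell in each. The medians were 1.96 and 1.35, with camera adjusted p of 1.2e-10 and 2.9e-08, and adjusted p = 0.21 and 0.26 with an estimated correlation. Oas2, a sensor of double-stranded RNA, was 32.4-fold higher in LeuA and 24-fold higher in LeuB. Isg15 (4.60 and 3.31, SE 0.09), Usp18 (4.09 and 3.69, SE 0.17) and the transcription factor Irf7 (4.09 and 3.10, SE 0.15) rose too. Of 17 NF-kappaB target genes, 7 rose in each leukaemia, and 4 fell in LeuA and 3 in LeuB. The medians were 0.08 and 0.16, with camera adjusted p of 0.18 and 0.058, and adjusted p = 0.58 and 0.46 with an estimated correlation. Camera called NF-kappaB target genes in both leukaemias with genes below the median left out (0.0124 and 0.0309), and in LeuB without LeuA 1 (0.0464) or LeuA 2 (0.0479). Tnfaip3 (2.30 and 2.37, SE 0.10), Traf1 (1.79 and 1.60, SE 0.13), Ier3 (1.94 and 1.33, SE 0.15) and Relb (2.93 and 2.54, SE 0.10) rose, although the second Relb probe gave 0.08 and -0.26 and was not called.

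Of 15 immediate early and stress genes, 9 rose (10 adjusted over the list alone) in LeuA and 8 in LeuB, and 1, Nr4a1, fell in each. The medians were 0.88 and 0.56, with camera adjusted p of 0.0054 and 0.066, and adjusted p = 0.18 and 0.27 with an estimated correlation. Klf6 (3.00 and 3.61, SE 0.13), Jun (2.59 and 1.51, SE 0.25), Egr1 (1.73 and 1.80, SE 0.22) and the antiproliferative gene Btg2 (1.43 and 1.47, SE 0.11) rose. Of 15 genes of the DNA methylation machinery, 7 fell and 2 rose in LeuA, and 8 fell and 3 rose in LeuB. The medians were -0.24 and -0.30, with camera adjusted p of 0.08 and 0.058, and adjusted p = 0.46 and 0.44 with an estimated correlation. Without LeuA 2 the DNA methylation machinery was called in both (0.0479 in each). In LeuB it was also called without WT 1 (0.0463), LeuA 1 (0.0375) or LeuB 3 (0.0498) and with slide as a block (0.0407), where 1 rose. Besides Tet1, the de novo methyltransferases Dnmt3a (-1.80 and -1.96, SE 0.26) and Dnmt3b (-1.43 and -1.57, SE 0.06) and the isocitrate dehydrogenase Idh2 (-1.20 and -1.72, SE 0.07) fell.

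Of 10 genes linked to activation by AML1-ETO, 4 rose in each leukaemia, and 1 fell (2 adjusted over the list alone) in LeuA and 2 in LeuB. The falls numbered 2 in LeuA without WT 1, WT 3 or LeuA 2, and 1 in LeuB without WT 1, WT 2, LeuA 1, LeuA 2, LeuA 3 or LeuB 2 and with slide as a block. The medians were 0.08 and 0.10, with camera adjusted p of 0.52 and 0.39. Id1 (1.69 and 1.61, SE 0.09), Ubash3b (0.81 and 1.87, SE 0.20) and Cdkn1a (1.42 and 1.05, SE 0.18) rose, and Bcl2 (-1.86 and -1.72, SE 0.10), which protects from apoptosis, fell. Without WT 1 and LeuB 3 the Ubash3b call in LeuA was lost (0.74, adjusted p = 0.0605). A second Cdkn1a probe gave 0.18 and 0.12 and was not called. Of 10 genes linked to repression by AML1-ETO, 6 fell in LeuA and 5 in LeuB, and 1, Cdkn2a, rose in each. Cebpa, Cebpe and Gfi1 of this list are also on the list of myeloid transcription factors, and another member on that of monocyte and macrophage genes. So this list is not separate evidence from those lists. The medians were -1.26 and -0.98, with camera adjusted p of 0.029 and 0.067, and adjusted p = 0.26 and 0.32 with an estimated correlation. LeuB was called as well with slide as a block (0.0407) and without WT 3 (0.0496) or LeuB 3 (0.0458). Cebpa, a master regulator of granulocyte commitment, was 38.9-fold lower in LeuA and 43.2-fold lower in LeuB.

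Of 14 BCL2 family genes, 5 rose and 3 fell in LeuA, and 4 rose (5 adjusted over the list alone) and 4 fell in LeuB. The medians were 0.03 and 0.17, with camera adjusted p of 0.63 and 0.69. The pro-apoptotic genes Bmf (2.83 and 2.19, SE 0.15), Bik (1.64 and 2.05, SE 0.12) and Bbc3 (1.83 and 1.66, SE 0.13) rose. Of 18 MYC and ribosome biogenesis genes, 8 fell in LeuA and 10 (12 adjusted over the list alone) in LeuB, and 2 rose in each. The medians were -0.13 and -0.29, with camera adjusted p of 0.22 and 0.048, and adjusted p = 0.58 and 0.46 with an estimated correlation. The LeuB call was lost without WT 1 (0.0534), WT 3 (0.0514) or LeuB 1 (0.111), after quantile normalization again (0.0572) and with genes below the median left out (0.0926). The nucleolin gene Ncl (-1.03 and -1.15, SE 0.11), Rrs1 (-0.43 and -0.75, SE 0.08) and Nolc1 (-0.38 and -0.55, SE 0.09) fell, and Rrp9 (0.62 and 0.28, SE 0.06) rose. Without WT 1 and LeuB 3 the Nolc1 call in LeuA was lost (adjusted p = 0.0574).

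Of 18 glycolysis and hypoxia genes, 6 rose (7 adjusted over the list alone) and 7 fell in LeuA, and 7 rose and 9 fell in LeuB. The medians were -0.16 and -0.22, with camera adjusted p of 0.77 and 0.55. The glucose transporter Slc2a1 (2.55 and 2.15, SE 0.12) and Ankrd37 (2.35 and 2.26, SE 0.13) rose, and Egln3, an oxygen-sensing hydroxylase (-4.64 and -4.74, SE 0.11), and Ndrg1 (-3.86 and -4.76, SE 0.20) fell. Of 14 adhesion and homing genes, 4 rose and 7 fell in LeuA, and 6 rose and 5 fell in LeuB, where 3 rose with slide as a block. The medians were -0.15 and 0.19, with camera adjusted p of 0.48 and 0.93, and in LeuB the mean of -0.21 had the opposite sign. The marrow homing receptor Cxcr4 (-4.34 and -4.30, SE 0.11), Vcam1 (-2.83 and -2.73, SE 0.21) and the selectin ligand Selplg (-2.15 and -1.40, SE 0.21) fell, and the integrin Itgb7 (3.11 and 3.79, SE 0.06) rose.

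Of 17 genes of cytokine receptors and signalling, 7 rose in each leukaemia, and 6 fell (8 adjusted over the list alone) in LeuA and 7 (9) in LeuB. The medians were -0.31 and -0.22, with camera adjusted p of 0.82 and 0.85. The receptor genes Il6ra (-6.15 and -4.89, SE 0.19) and Il3ra (-4.13 and -4.62, SE 0.25, with -5.32 in LeuB with slide as a block) fell, and the receptor gene Csf2rb2 (4.37 and 3.38, SE 0.13) and the STAT5 target Cish (4.39 and 3.79, SE 0.13) rose. Ptprc, which encodes CD45, fell by 2.53 and by 2.44 (SE 0.09). Of 9 housekeeping genes, 3 fell in LeuA and 4 in LeuB, with medians of -0.12 and -0.10 and camera adjusted p of 0.44 and 0.37. Hprt fell by 0.26 and by 0.34 (SE 0.06), and Rpl13a fell by 0.47 in LeuB (SE 0.08) and gave 0.12 in LeuA (adjusted p = 0.32). Sdha fell by 0.19 and by 0.41 (SE 0.06), but its LeuA call was lost without WT 1, WT 2, WT 3, LeuA 1, LeuA 2, LeuB 2 or LeuB 3 (adjusted p 0.0503 to 0.132). Tbp fell by 0.21 and by 0.23 (SE 0.07), and its LeuA call was lost without WT 1, WT 2, WT 3, LeuA 2, LeuA 3 or LeuB 2 (0.0614 to 0.153) and its LeuB call without WT 2, WT 3, LeuB 2 or LeuB 3 (0.0704 to 0.0847) and with slide as a block (0.262). The number of housekeeping genes that fell in LeuA was 1 without WT 1, WT 2, WT 3, LeuA 2 or LeuB 2.

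**Figure D2:**
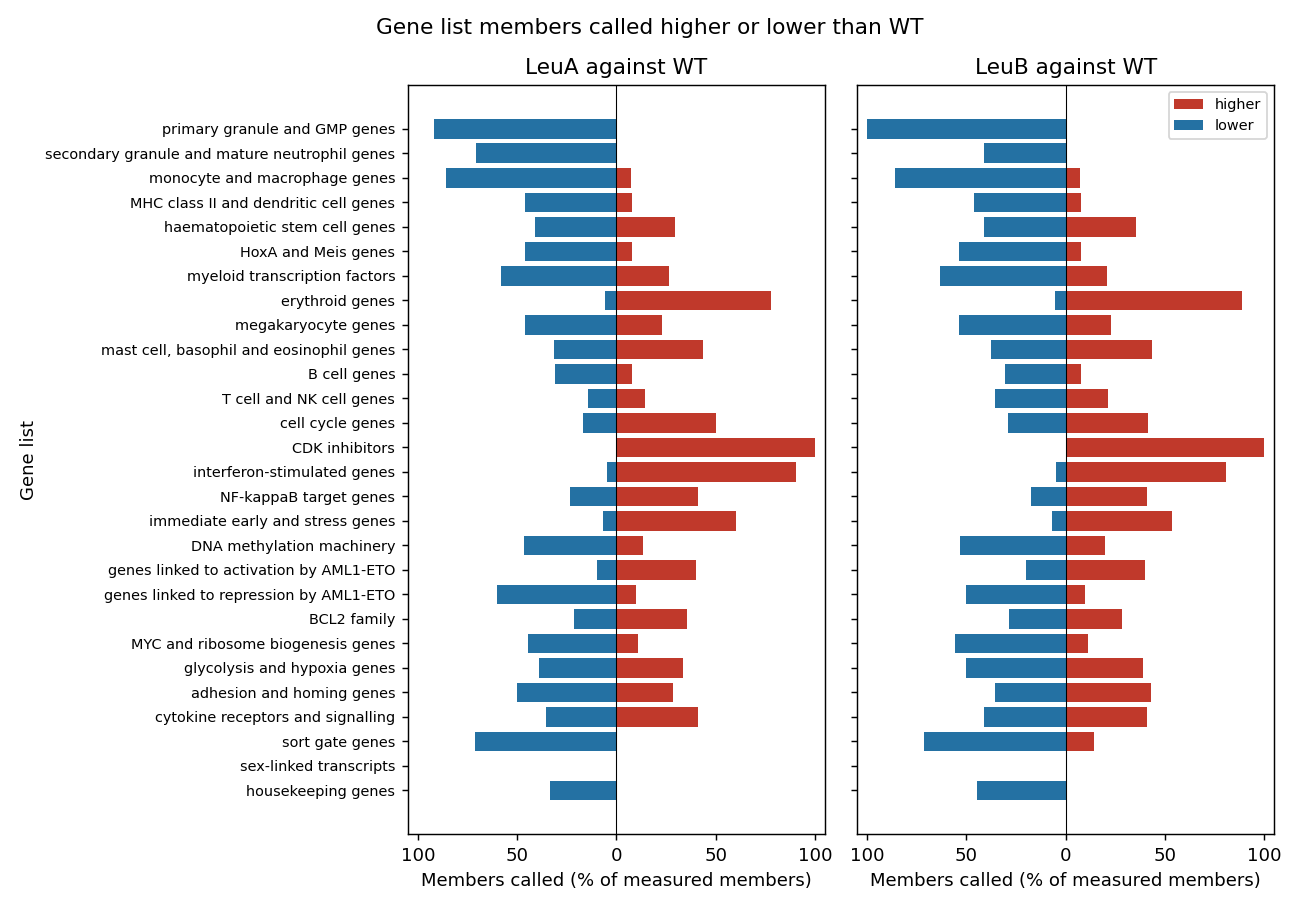
Percent of the measured members of each gene list that were called higher (to the right) or lower (to the left) against WT, in 1 panel for LeuA and 1 for LeuB. All 7 CDK inhibitors were called higher in both leukaemias, and 12 of 12 primary granule and GMP genes were called lower in LeuB.

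The leukaemias shared most of these changes. Of the genes called, 6805 changed in the same direction in LeuA and LeuB, 3344 higher and 3461 lower, and 72 in opposite directions. Independent lists of these sizes would share 852 higher and 847 lower genes. Both comparisons use the same 3 WT arrays, and the counts were not made with separate WT arrays. With different WT arrays for each leukaemia, the change in LeuB 2 and LeuB 3 had a slope of at least 0.89 on that in LeuA over all genes. In 20 simulations of unchanged groups against shared controls limma called a mean of 0 genes in both, and the changes of both groups correlated across genes at 0.5. The observed correlation across genes, which are not independent replicates, was 0.937, with a covariance of 0.998 against 0.0136 in the simulations. The sign was the same in 77.5% of genes, against 66.7% in the simulations. The number changed in the same direction was 6301 with slide as a block. The 72 genes with opposite changes also had a called difference between the leukaemias. Among them were Xlr3b (-3.76 and 1.67, SE 0.11) and Rap1gap (3.02 and -1.55, SE 0.20), and, chosen after their values were seen, the transcriptional regulator Lmo4 (1.05 and -1.94, SE 0.19) and the amino acid transporter Slc7a8 (-1.10 and 1.42, SE 0.16).

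**Figure D3:**
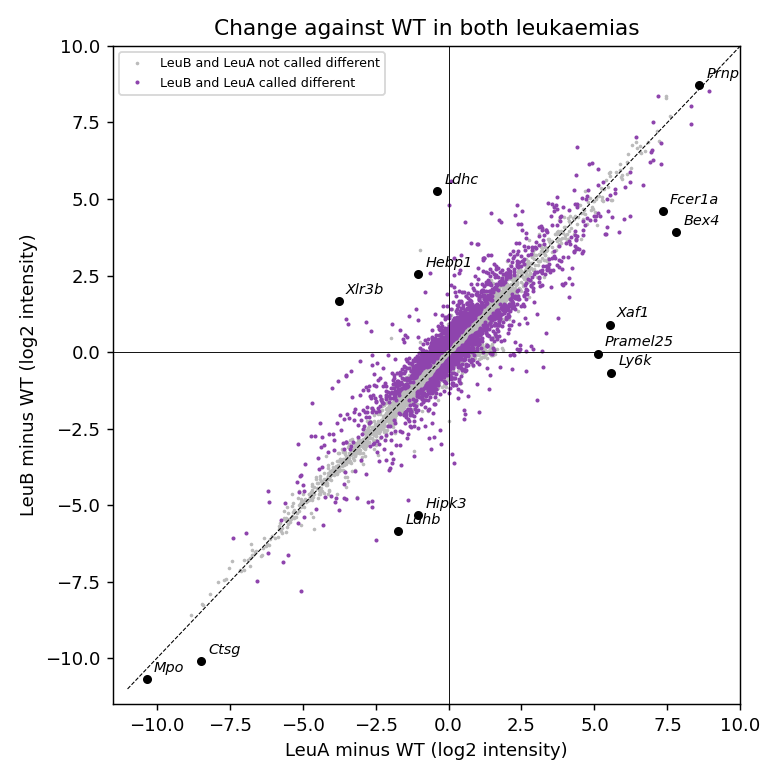
Log2 change in LeuB against WT (y axis) over that in LeuA against WT (x axis) for each of 21872 genes, with the genes called between the leukaemias in colour. The correlation across genes is 0.937, and 2683 genes differ between the leukaemias.

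LeuB differed from LeuA in a smaller set of genes, and several of them lay near the bottom of the scale in 1 of the leukaemias. Ldhc, the lactate dehydrogenase of germ cells, was 49.9-fold and Amph, the gene of amphiphysin, 45.2-fold higher in LeuB, where they had means of 12.15 ± 0.15 and 11.79 ± 0.03 (SD, n = 3) against 6.51 and 6.29 in LeuA. The X-linked genes Xlr3b and Xlr4b were 43-fold and 24.3-fold higher, and the T cell adaptor gene Skap1 was 27.5-fold higher by its brightest probe, whose change in LeuB against WT was 4.79 where its other probes gave 0.53, 0.44 and 0. The lipid transporter gene Abca3 was 20.6-fold, the tetraspanin gene Tspan32 14-fold and the haem-binding protein gene Hebp1 12-fold higher, which is 3.59 on the log2 scale, or 2.99 with slide as a block. Ly6k was 75.8-fold, Pramel25 35.8-fold, the interferon-induced Xaf1 24.5-fold, Rap1gap 23.8-fold, the kinase gene Hipk3 19.6-fold, the lactate dehydrogenase gene Ldhb 17.3-fold, Bex4 14.8-fold and the co-chaperone gene Bag3 13.7-fold lower in LeuB. Their adjusted p lay between 1.7e-10 and 0.00024, and the arrays of LeuA and LeuB did not overlap in any of these 16 genes, as the naming rule required.

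Of the 2683 genes (12.3%) called in LeuB against LeuA, 1511 were higher and 1172 lower in LeuB, 377 differed at least 2-fold (207 higher, 170 lower) and 5 at least 32-fold. The arrays did not overlap in 6602 genes, where chance gives 10%. With slide as a block, which leaves LeuB 1 as the only LeuB array on the slide of LeuA, 869 genes were called, 764 of them among the 2683, and on slide 1 alone 581. The count was 1727 without LeuA 2, 1674 without LeuA 3, 5498 without LeuB 1, 1380 without LeuB 2, 1503 without LeuB 3 and 1409 without both WT 1 and LeuB 3. Without LeuB 1 the leukaemias lie on different slides, so 5498 includes any effect of the slide.

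Interferon-stimulated genes differed most as a list between the leukaemias: 11 of 21 were lower in LeuB than in LeuA (12 adjusted over the list alone) and 1, Gbp2, was higher. The median difference was -0.43, with camera adjusted p of 3.6e-07, and adjusted p = 0.27 with an estimated correlation. Isg15 (-1.29, SE 0.09) and Irf7 (-0.99, SE 0.15) were lower besides Xaf1. The interferon-stimulated genes called lower numbered 7 without LeuA 2, 7 without LeuB 2, 6 without LeuB 3 and 4 with slide as a block, where the list call was kept (5.1e-06). Gbp2 was not called without WT 2, WT 3, LeuA 2, LeuA 3, LeuB 2 or LeuB 3 or with slide as a block. Adhesion and homing genes were the second list called, with 4 of 14 higher in LeuB, a median of 0.08 and camera adjusted p of 0.044, and adjusted p = 0.42 with an estimated correlation. This call was lost with slide as a block (0.0742), without LeuA 3 (0.0767), without LeuB 1 (0.0965), without LeuB 3 (0.101) and with genes below the median left out (0.0684). Itgb7 (0.68, SE 0.06) and Selplg (0.76, SE 0.21) were higher. The other 26 lists had medians between -0.24 and 0.27 and camera adjusted p between 0.051 and 0.95. Camera with slide as a block also called mast cell, basophil and eosinophil genes (0.0142), MYC and ribosome biogenesis genes (0.0162) and immediate early and stress genes (0.0264), for which adjusted p = 0.46, 0.54 and 0.27 with an estimated correlation. Mast cell, basophil and eosinophil genes were also called without WT 2 (0.036), LeuA 2 (0.0273), LeuB 2 (0.037) or LeuB 3 (0.0249), and immediate early and stress genes without LeuA 1 (0.0453), LeuA 2 (0.0479) or LeuB 2 (0.0335). Without LeuA 2, CDK inhibitors (0.0302) and glycolysis and hypoxia genes (0.0081) were called, for which adjusted p = 0.32 and 0.58 with an estimated correlation. Median and mean differed in sign for haematopoietic stem cell genes (0.09 and -0.02), HoxA and Meis genes (-0.13 and 0.04), NF-kappaB target genes (0.01 and -0.08), BCL2 family genes (-0.05 and 0.13), genes of cytokine receptors and signalling (-0.04 and 0.04) and T cell and NK cell genes (-0.01 and 0.11).

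Several genes named above differed between the leukaemias in amount while changing the same way against WT. Tph1 was 1.82-fold and Fcer1a 6.61-fold lower in LeuB than in LeuA, and the granule protease Ctsg was 3.01-fold lower. Tac2 (2.3-fold), the B cell receptor subunit Cd79b (3.9-fold), Pbx3 (3-fold) and Il6ra (2.4-fold) were higher. Of the calls between the leukaemias among named genes, 21 were lost with slide as a block (adjusted p 0.0566 to 0.607), among them Tet2, Slamf1, Ddc, Jun, Selplg, Il6ra and Cish. The number lost was 15 without LeuB 2 (0.0528 to 0.153), 11 without LeuA 3 (0.0541 to 0.147), 9 without LeuB 3 (0.0531 to 0.147), 8 without LeuA 2 (0.0528 to 0.148), 6 without LeuA 1 (0.0511 to 0.0988), 6 without WT 3 (0.0535 to 0.077), 5 without WT 2 (0.0568 to 0.0747), 3 without WT 1 (0.0504 to 0.0689) and 1, Selplg, without LeuB 1 (0.0669). Without LeuB 1 the slide may add to the differences, so calls kept there are not a check against the slide.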

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

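The tests of the 3 patterns weighed here, with their criteria, were chosen after the patterns were seen, as were the genes Chil3, Csf3r, Ly6g, Lyz2, Ctss, Xlr, Xlr3a, Xlr4a and Xlr4d-ps, and the splits of the arrays were planned. LeuA and LeuB changed by different amounts against WT in 2683 genes, by the test of the difference itself. On the log2 scale, values below are LeuB minus LeuA, and a negative value means lower in LeuB.

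Among interferon-stimulated genes, the list as a whole (median -0.43), Xaf1 (-4.62), Isg15 (-1.29) and Irf7 (-0.99) were lower in LeuB. The list had adjusted p = 0.27 with an estimated correlation, and 4 of its genes instead of 11 were called lower with slide as a block. For the genes of the genotype the differences were -0.37 for Tet2, -0.90 for Runx1 and -1.20 for Runx1t1. The Tet2 call was lost with slide as a block (-0.32, adjusted p = 0.0918) and with the mean of both probes (-0.15, adjusted p = 0.239), and the Runx1t1 call without LeuB 2 (0.0528) and on slide 1 alone (0.0961). Genes of the sort gate gave 0.69 for Fcgr2b and 0.64 for Slamf1, which gave 0.41 and was not called with slide as a block. Genes strongly higher in LeuB were Ldhc (5.64), Amph (5.50), Xlr3b (5.43), Skap1 (4.78), Xlr4b (4.60), Abca3 (4.36), Tspan32 (3.81) and Hebp1 (3.59). Genes strongly lower in LeuB were Ly6k (-6.24), Pramel25 (-5.16), Rap1gap (-4.57), Hipk3 (-4.29), Ldhb (-4.12), Bex4 (-3.89) and Bag3 (-3.78).

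Differences in lineage genes were -1.59 for the granule protease Ctsg, -2.72 for Fcer1a and -1.17 for Cma1 of mast cells, 0.33 for Gp5 and -0.68 for Itgb3 of megakaryocytes, 1.97 for Cd79b and 0.53 for Vpreb1 of B cells, and 0.82 for Gata3 and 1.00 for Lat of T cells. Stem cell and Hox partner genes gave -0.66 for Ctnnal1 and 1.58 for Pbx3. Adhesion and cytokine signalling genes gave 0.68 for Itgb7, 0.76 for Selplg, 1.26 for Il6ra, -0.98 for Csf2rb2, -0.60 for Cish and 1.06 for Ubash3b. Stress and NF-kappaB genes gave -1.08 for Jun, 0.61 for Klf6, -0.61 for Ier3 and -0.39 for Relb. Genes of metabolism gave -0.86 for Tph1, -0.28 for Ddc, -0.52 for Idh2 and -0.89 for Ndrg1. The tachykinin gene Tac2 gave 1.20 and the pro-apoptotic Bmf -0.64. Ribosome biogenesis and housekeeping genes gave -0.31 for Rrs1, -0.34 for Rrp9, -0.22 for Sdha and -0.59 for Rpl13a. With slide as a block, LeuB 1 is the only LeuB array on the slide of LeuA. In that fit Cma1, Gp5, Itgb3, Vpreb1, Lat, Selplg, Il6ra, Cish and Ubash3b were not called. Nor were Jun, Klf6, Ier3, Relb, Ddc, Ndrg1, Bmf, Rrs1, Rrp9 and Sdha. Vpreb1 and Gp5 then each gave 0.21, whereas Cma1 gave -1.44. Outside the gene-level tests, 813 probes with no gene name were higher in both leukaemias than in WT.

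For the genes called in the same direction in both leukaemias, 1 of 100 drawn splits of the 9 arrays, the real one, gave as many. It gave 6805 genes, against a highest other of 108. Almost all possible splits mix WT with leukaemic arrays, which differ most. So the test argues against chance for WT against leukaemia, and does not bear on which leukaemic arrays form LeuA or LeuB. The arrays of a leukaemia also descend from 1 primary mouse. For the number of list calls, 6 of 100 splits called as many lists, with 24 for the real one and 27 for the highest other. Splits with unequal shares of WT arrays still hold part of the difference between WT and leukaemia. So the splits cannot decide whether chance gives as many list calls, and chance is not excluded by them. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real splits gave 8049, 9241 and 2683 genes for LeuA, LeuB and LeuB against LeuA, and limma called 0 in each of the others, where up to 540, 1810 and 3147 genes had an unadjusted p under 0.05.

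In both leukaemias granulocyte-monocyte genes were low and erythroid genes high. A minority of other cells among WT-like GMPs would leave primary granule and GMP genes at much of their WT level, but their medians were -6.72 in LeuB and -6.76 in LeuA. The row of the array on the slide is argued against by LeuB 2 and LeuB 3, which lie in the row of the WT arrays: their changes against WT had a slope of 0.95 on the LeuA changes over genes called in LeuA, near the 0.96 of LeuB 1, and of at least 0.89 over all genes with different WT arrays on the 2 sides. Cells of another type as the larger part of the sorted leukaemic cells stay open, since Fcgr3 and Fcgr2b of the gate fell, and so do genotype and the donor tissue that changed with it, as untested.

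Neutrophil granule genes were high in LeuB 3. There 3 of 14 monocyte and macrophage genes (F13a1, Lyz2 and Ctss) were also higher by more than 1 than in the other LeuB arrays. So were 1 of 13 MHC class II and dendritic cell genes (H2-Ab1), 1 of 12 primary granule and GMP genes (Mpo) and 1 of 18 erythroid genes. The medians of these 4 lists were 0.37, 0.12, 0.23 and 0.12. WT-like GMPs in LeuB 3 are argued against by the primary granule and GMP genes. These gained a median of 0.07% of the WT signal in LeuB 3 over the other LeuB arrays, where the secondary granule genes gained 26.5%. The second slide is argued against by LeuB 2 on the same slide. LeuB 3 differed from it by a median of 1.03, against 0.94 from LeuB 1. Mature neutrophils may be a source, and this cannot be told apart from such transcripts in the progenitors: the median of 0.98 lay at percentile 100 of 10000 random lists, but only 8 of 17 members were higher by more than 1. The largest differences from the other LeuB arrays were in S100a9, S100a8 and Chil3, at 12.99, 11.24 and 10.18 in LeuB 3, gains of 40.1%, 23.7% and 77.4% of the WT signal, whereas Padi4 (6.55) and Csf3r (15.25) gained 1.17% and 1.24%. The lineage-negative gate would remove such cells, 8 of the list's genes had WT means of at least 9 in GMPs, Csf3r and Ly6g are also in other lists, and other mature myeloid cells were not tested as a source.

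Of 9 Xlr genes measured, which lie on the X chromosome, 4 were low in LeuA and above WT in LeuB, whereas Xlr rose in both (2.11 and 1.62) and Xlr3a rose by 0.73 in LeuB. The slide is argued against by slide 1 alone, where LeuB 1 exceeded LeuA by 2.35 to 5.23 in the genes of this pattern, which were Xlr3b, Xlr4a, Xlr4b and Xlr4d-ps. If these genes are read from 1 parental X only, they are on in about 1 of 2 WT cells. A different active X chromosome in each leukaemia as the whole cause of the rise in LeuB would then double them, 1 on the log2 scale. Whether they are read in this way was not tested. This cause cannot be told apart from others: the mean rise was 1.48 (SE 0.08 over arrays), but the genes were chosen for a rise. Xlr4b (1.09, SE 0.07) lay within 2 SE of a doubling. Xlr4a (1.19, SE 0.08), Xlr3b (1.67, SE 0.11) and Xlr4d-ps (1.96, SE 0.15) lay above it. That each gene is compared, and not their mean, was decided with the values known. For the low level in LeuA it stays open too, and probes shared between these related genes, loss of DNA methylation and other differences between the leukaemias were not tested.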

How the results depend on the processing

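The omission of both WT 1 and LeuB 3 was chosen after seeing the data, and the other alternatives were planned. Of 6607 values of named genes under the alternatives, 6371 kept their side of the threshold, 221 lost their call, 15 gained one and 0 changed direction. The number of genes called in LeuB against LeuA depended most on the setting: 6194 with array weights, 1783 with only the groups compared, 869 with slide as a block, 581 with slide 1 alone, 1158 at an adjusted p under 0.01, 377 with at least 1 on the log2 scale, and 1409 without both WT 1 and LeuB 3. Leaving out each array in turn gave 1380 to 5498, with 5498 without LeuB 1, 1380 without LeuB 2, 1503 without LeuB 3, 1727 without LeuA 2 and 1674 without LeuA 3. Without LeuB 1 slide and group coincide for LeuB, so 5498 includes any effect of the slide. A stricter threshold lowers the count by construction, and for the other settings the cause was not tested. With at least 1 on the log2 scale, which is stricter by construction, 2838 genes were called in LeuA against WT, 3013 in LeuB against WT and 2458 in the same direction in both. The other alternatives kept these 3 counts within 1.5 times. Leaving out each array in turn gave 7073 to 8591 genes in LeuA, 8003 to 10822 in LeuB and 6020 to 6979 in the same direction in both. The counts of 10822 and 6979 came without LeuB 1, where the same limit of the slide holds. Of 84 list tests, camera called 0 with an estimated correlation, where 14 had an unadjusted p under 0.05, and fry called 60. Fry asks whether a list changes at all rather than more than other genes. With an estimated correlation, LeuA calls were lost even where the estimate was -0.05 (CDK inhibitors) or 0 (immediate early and stress genes). So correlation among the genes of a list does not explain the loss in these 2 lists. In that setting camera also tests on the 6 residual degrees of freedom and not on the number of genes, which lowers power. How far this accounts for the loss was not tested. Omission of each array gave 21 to 30 list calls. Detection flags and background levels were not used here, so values near the bottom of the scale, 5.66, bound how large a fall, or a rise from there, could be measured. The top, 18.24, was the same in every array, so the fold of Mpo rests on the top rank of a shared distribution.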

Other observations

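The genes in this part were chosen after their values were seen. Of 9 measured genes of the HoxC cluster, which code for transcription factors of body patterning, 4 rose in LeuA and 3 in LeuB, whereas 6 of 13 HoxA and Meis genes fell in LeuA and 7 in LeuB. Hoxc4 rose by 6.57 in LeuA and by 6.53 in LeuB (SE 0.13), to means of 12.98 and 12.93 from 6.40 in WT. Hoxc5 (2.89 and 3.21, SE 0.18) and Hoxc9 (2.12 and 3.20, SE 0.20) rose as well, and Hoxc6 rose by 1.90 in LeuA (SE 0.15) and gave 0.41 in LeuB with adjusted p of 0.052, a difference of -1.48 between the leukaemias. The 9 HoxD genes measured had WT means of 5.95 to 6.32, near the bottom of the scale.

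Besides Tph1 and Ddc, the monoamine oxidase gene Maob rose (3.73 and 3.64, SE 0.18), whereas Maoa fell (-1.17 and -1.04, SE 0.08). The serotonin transporter gene Slc6a4 gave 0.07 and 0.04, with adjusted p of 0.45 and 0.7. The metallothionein genes Mt2 (7.16 and 7.21, SE 0.27) and Mt1 (2.14 and 2.13, SE 0.09), whose products bind zinc, rose. So did the transcription factors Wt1 (7.29 and 6.84, SE 0.09), Gfi1b (4.29 and 3.86, SE 0.31) and Mitf (1.61 and 1.35, SE 0.07), and the surface receptor gene Cd200r3 (5.53 and 5.75, SE 0.12). Of 30 Pramel genes measured, 3 rose in LeuA and 1 other in LeuB. In LeuA Pramel25 (5.11), Pramel29 (3.19) and Pramel51 (2.20) rose, where LeuB gave -0.05, 0.05 and -0.05, and the difference between the leukaemias was called for each. All 3 were highest in LeuA 1, at 12.04, 10.11 and 9.41. Whether their probes read the same transcript was not tested, so they may not be separate rises.

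Some genes jumped in 1 array by more than 2 on the log2 scale while the other arrays of the group lay within 0.5. Their numbers were 15, 53 and 15 in WT 1, 2 and 3, then 32, 67 and 35 in LeuA 1, 2 and 3, then 2, 3 and 4 in LeuB 1, 2 and 3. An example is Hoxb13, at 11.46 in WT 2 and 6.09 in the other WT arrays. Among 13000 probes with no gene name, 2065 were called in LeuA and 3365 in LeuB, with 813 higher and 830 lower in both.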
